A study of Mus musculus with 32 samples.

How the data were processed

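RNA of hindlimb muscle was measured in C57BL/6 mice of 2 ages, young at 8 weeks and aged at 80 weeks, on GeneChip Mouse Gene 2.0 ST arrays, which carry short oligonucleotide probes for whole transcripts. The mice were kept in a cycle of 12 h light and 12 h darkness, and muscle was taken at zeitgeber time (ZT, hours after lights on) 0, 3, 6, 9, 12, 15, 18 and 21, over 16 sampling times on 2 successive days. Each array held a pool of RNA of 3 mice, per the labels, so that the 32 arrays stand for 96 mice. The labels put the arrays in 16 groups, each of 1 age and 1 ZT, with 2 arrays per group. Each array of a group is thus a pool of other animals, and the spread between the arrays of a group is that between pools, which hides the spread between single mice. The labels number the repeats 1 and 2 and do not state that a number marks a day.

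The values are those of a single table of the authors. The deposited values are log2 expression levels of 24479 probe sets on all 32 arrays, made with R 3.2.2 and the affy package 1.44.1 by the robust multi-array average method (RMA), per the submitters' processing notes. RMA corrects background, normalises arrays by quantiles and summarises the probes of a probe set, and it shrinks the differences of weakly expressed genes. The definition of the probe sets and the genome build are not given in the sources used here, so no coordinates are given. The values ran from 1.70 to 13.7, and the array medians from 5.98 to 6.08. The sorted values of 2 arrays differed by up to 0.299, so that the columns of the table are not exactly quantile normalised. Arrays have no read depth, and their number limits the precision here.

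Of the probe sets, 23281 had 1 gene symbol, 0 had several and 1198 had none in the platform annotation used here. Symbols were updated through the RefSeq table of assembly GRCm38.p6, which held 23155 of the identifiers and served only for names, gene classes and which genes neighbour each other. Of probe sets that share a symbol the one with the highest mean over all arrays was kept, which left 23279 genes, and no filter on level was applied. No pair of arrays was a duplicate. The smallest root mean square difference between any 2 arrays was 0.236 on the log2 scale, and repeats of a group differed by 0.263 to 0.382.

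The tests were run with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and adjusted p-values of single genes in the text are limma's. Rhythm was tested with a cosinor model that has a mean, a cosine and a sine of period 24 h per age, fitted to all 32 arrays, by a moderated F test on the cosine and sine of each age. The same test on a common cosine and sine gave the genes rhythmic with ages together, and the difference of the cosine and sine between ages was tested in the model with separate terms. The amplitude is the distance from the mean to the peak on the log2 scale, and the peak time comes from the fitted curve. Standard errors of peak times are approximations from the standard error of the amplitude. The age difference was tested with ZT as an additive factor of 8 levels, the dependence of the age difference on ZT in a model of 16 groups, and a 12 h component in the cosinor model with added 12 h terms.

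Median peak shifts and median log2 amplitude ratios of aged over young were compared by two-sided permutation tests of 100000 draws, which swapped the age labels within ZT after each gene had been centred per age. The spread between repeats was compared by an exact permutation test over 256 swaps of age within ZT. The likeness of the repeats in further hepatocyte genes was measured by their difference and as an intraclass correlation over the 16 groups, with 95% limits from 100000 bootstrap draws of groups and from the F distribution. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 34 lists. Enrichment of rhythmic genes in a list was tested with a one-sided Fisher's exact test. It takes genes as independent, which genes of a list are not.

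The design, the alternatives, the gene lists and the rule for named genes were written before the data were examined. The 34 lists held 416 entries, of which 385 were measured. They covered clock genes and clock output, responses to heat and glucocorticoids, metabolism, matrix, innervation, atrophy, immune and stress genes, and 17 lists of fibre types and of other cell types that a muscle sample can hold. A list of 18 hepatocyte genes was added after the data had been seen, and 20 further hepatocyte genes were listed before their values were looked at. The rule names all genes of the clock lists, the 12 other rhythmic genes of largest amplitude, the 12 largest rises and the 12 largest falls with age among genes on the same side at all 8 ZT, up to 4 members per list, and the leading genes of the other tests.

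The functions that run these tests were tested on simulated data with the spread of the 23279 genes. Age differences of 0.3 on the log2 scale were recovered in 74.7% of cases and those of 0.6 in 96.6%. A rhythm of amplitude 0.3, simulated alike in both ages, was recovered in 61.4% of cases in young and 51.4% in aged. A further 200 rhythms of amplitude 0.6 were placed in young alone, and 85.5% of them were called different between ages. These can loosen the Benjamini-Hochberg threshold in young only, so the gap does not show lower power in aged. The noise was drawn for each gene independently. False calls made up 3.26% to 5.31% of the calls.

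The alternatives were quantile normalisation again, centring of arrays, a filter on level, all probe sets, other variance models, array weights, the repeat number as a block, a fibre type covariate, ZT as a factor, other models of time, and leaving out each array and each repeat number. After the data had been seen, alternatives without 6 arrays that carried liver transcripts, with hepatocyte, adipocyte and array range covariates, and with age by repeat as a random block were added.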

Results

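Hindlimb muscle of young and aged mice was profiled around the clock, with 16 arrays per age and 2 arrays at each of 8 times of day. The design asks which transcripts of muscle follow the time of day, which differ with age, and whether the daily rhythm itself differs between the ages. All 32 arrays had low Xist (4.86 on average in young and in aged) and clear Y-linked expression (Uty at 8.16 in young and 8.52 in aged), so that they were alike in this respect.

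Muscle of both ages showed a strong molecular clock. In young muscle Nr1d1, which encodes the repressor REV-ERBα, varied 6.57-fold between trough and peak and peaked at ZT 5.72 ± 0.301 (SE, n = 16). Per1 varied 5.47-fold with its peak at ZT 12.4, and Arntl, which encodes BMAL1 of the activating arm of the clock, varied 4.91-fold with its peak at ZT 23.8, opposite in phase to Dbp (3.93-fold, ZT 11.7), a transcription factor gene driven by the clock. In aged muscle the same genes varied 5.20-fold (Nr1d1), 3.78-fold (Per1) and 4.50-fold (Dbp). Each of the 4 genes, Arntl included, was rhythmic in both ages (adjusted p from 4.78e-10 to 6.85e-06).

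**Figure D1:**
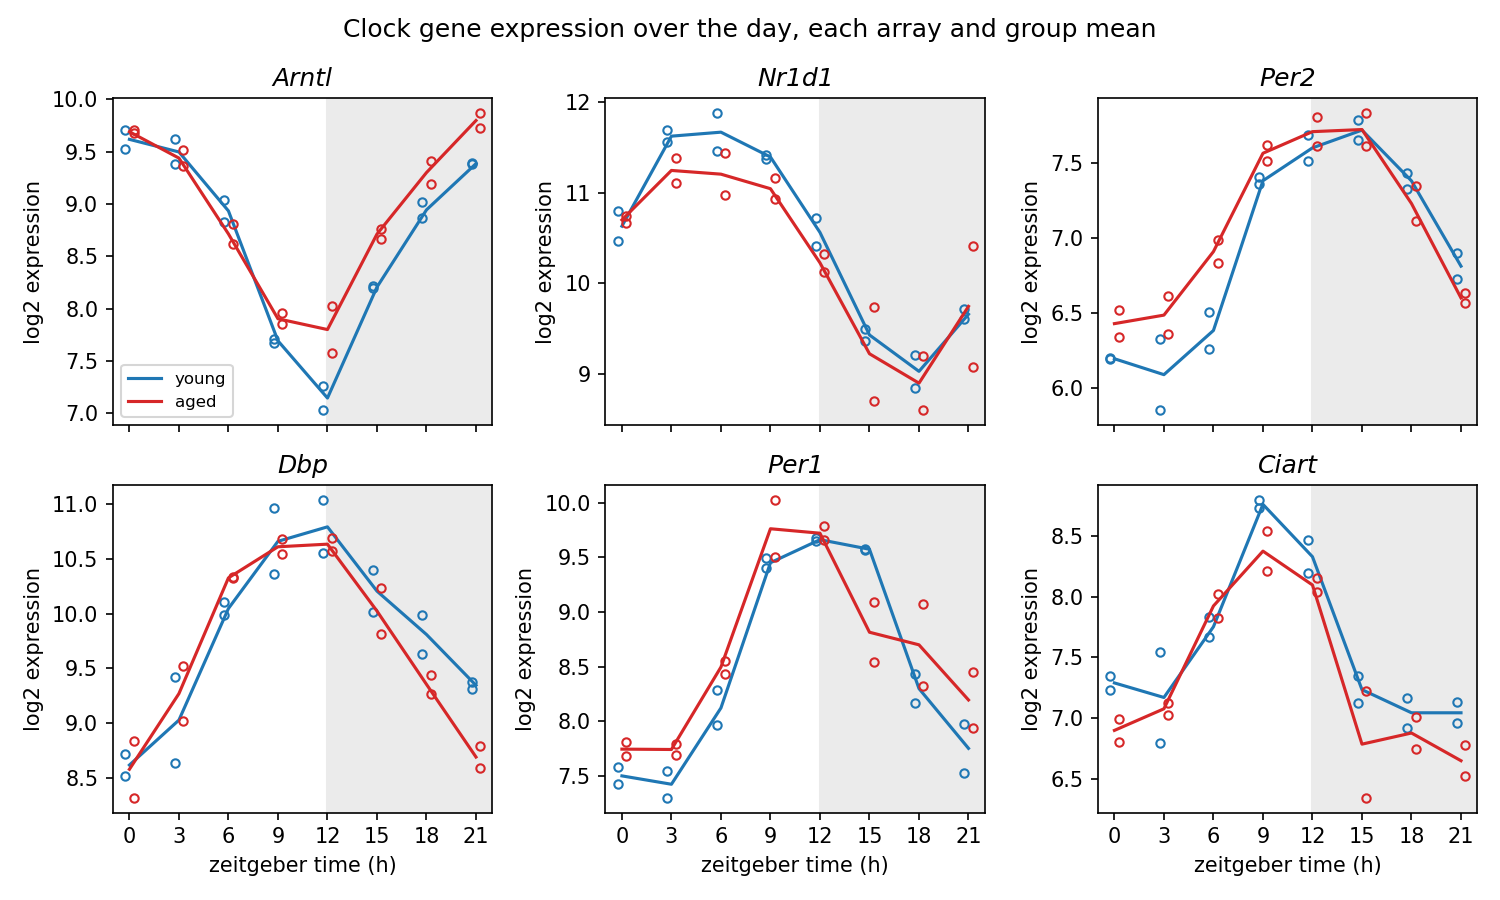
Log2 expression of 6 clock genes (vertical axes) against zeitgeber time in h, with each array as an open circle, lines through the means of 2 arrays, young in blue and aged in red, and the dark phase shaded. Arntl is highest near ZT 0, Nr1d1 in the light phase, and Per1, Per2, Dbp and Ciart around the change from light to dark.

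Of 15 measured core clock genes 14 were rhythmic in young, 14 in aged and 14 with ages together (15 adjusted over the list alone), and the exception over all genes was Rora. Of 13 clock output genes 10 were rhythmic in young, 9 in aged and 11 with ages together (12 adjusted over the list alone). Both lists were enriched in rhythmic genes by Fisher's exact test (adjusted p = 2.68e-18 and 1.01e-13). Nampt and Dtx4 did not pass the test with ages together (adjusted p = 0.761 and 0.173).

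Over the whole genome 448 genes were rhythmic in young muscle and 162 in aged muscle, 126 of them in both, where independent lists of these sizes would share 3.12. With ages together 837 genes were rhythmic, with a median amplitude of 0.20, a 1.33-fold change from trough to peak. Their peaks fell in every part of the day, from 81 genes between ZT 6 and ZT 9 to 128 genes between ZT 18 and ZT 21. With ZT as a factor in place of the cosinor the count of genes rhythmic in young was 104, that of genes rhythmic in aged 32 and that of genes rhythmic with ages together 309, and with each age fitted alone the counts were 292 in young and 98 in aged. With array weights they were 483 in young and 255 in aged, which is a smaller gap in ratio. Without the 6 arrays that carried liver transcripts, given at the end, they were 255 in young, 108 in aged and 585 together.

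Outside the clock lists the largest rhythms included genes of glucose handling. Pfkfb3, which encodes an activator of glycolysis, varied 4.30-fold in young and 3.50-fold in aged muscle, with peaks at ZT 4.75 and ZT 4.73. Ppp1r3c, which encodes a glycogen-targeting subunit of protein phosphatase 1, varied 3.37-fold in young and 2.16-fold in aged, with peaks at ZT 20.4 in both. Arrdc2 and Arrdc3, members of the arrestin domain family, varied 3.78-fold and 2.86-fold in young and peaked in the dark phase. Slc25a25, a mitochondrial carrier gene, varied 2.95-fold in young (adjusted p = 0.00459) and did not pass the test in aged (adjusted p = 0.230). Angptl7, Cep85l, Pnpla3, Hspa1a, Ifi205, Banp and Slc25a30 completed the 12 largest amplitudes.

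Of 13 glucocorticoid target genes 11 were rhythmic with ages together (12 adjusted over the list alone), 8 in young and 4 in aged (Fisher's exact test, adjusted p = 1.01e-13). Fkbp5 peaked at ZT 18.9 in young and varied 2.89-fold, against 1.89-fold in aged. Tsc22d3, Zbtb16 and Pik3r1 peaked between ZT 17.0 and ZT 19.5 in young. Of 15 heat and cold response genes 8 were rhythmic together (8 adjusted over the list alone; adjusted p = 1.18e-07 for the list), 1 in young and 0 in aged by limma. Dnajb1, a heat shock chaperone gene, peaked at ZT 18.5 in young, and Hspa1a and Hspa1b, near-identical copies that can share probes, passed with ages together only. Of 17 genes of glucose and glycogen metabolism 4 were rhythmic together (4 adjusted over the list alone; adjusted p = 0.0115 for the list), namely Pfkfb3, Ppp1r3c, Pdp1 and Tbc1d1.

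Lists of other cell types and of fibre state also passed Fisher's exact test for rhythmic genes, which takes genes as independent. By camera the estimated correlation within the lists was 0.41 (endothelial), 0.58 (macrophage), 0.13 (atrophy and autophagy) and 0.84 (slow fibre). These p-values therefore describe the lists and do not measure chance for correlated genes. Of 10 endothelial genes 5 were rhythmic together (7 adjusted over the list alone; Fisher's exact test, adjusted p = 8.75e-05), and Kdr, the receptor for vascular endothelial growth factor, varied 1.93-fold in young with its peak at ZT 1.85. Of 12 macrophage genes 4 were rhythmic together (6 adjusted over the list alone; adjusted p = 0.00369 for the list), among them Cd163, which passed in aged with a peak at ZT 19.1 and not in young (adjusted p = 0.152). Of 15 atrophy and autophagy genes 4 were rhythmic (7 adjusted over the list alone; adjusted p = 0.00801 for the list), among them Foxo1 and Trim63. Of 12 slow fibre genes 3 were rhythmic (10 adjusted over the list alone; adjusted p = 0.0302 for the list), namely Casq2, Atp2a2 and Tnnc1. These 3 did not pass without the 6 arrays with liver transcripts (adjusted p = 0.0613, 0.119 and 0.140), but the amplitudes there were 0.30, 0.47 and 0.52, against 0.29, 0.45 and 0.52 over all arrays, so that the rhythm of Casq2, the rhythm of Atp2a2 and the rhythm of Tnnc1 were about as large in the fewer arrays. With the adipocyte mean as a covariate, chosen after seeing the data, the amplitudes were 0.26, 0.34 and 0.40 (adjusted p = 0.0784, 0.171 and 0.172), and with the slow minus fast fibre mean 0.11, 0.067 and 0.071 (adjusted p = 0.485, 0.680 and 0.740). The 3 genes are part of the latter mean, which lowers their amplitudes by construction, so that the mix of fibres in the pools was not set apart from a rhythm within fibres.

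Clock genes peaked earlier in aged than in young muscle. Per2 peaked at ZT 14.0 ± 0.232 (SE) in young and ZT 12.7 ± 0.277 in aged, Arntl at ZT 23.8 ± 0.272 and ZT 22.6 ± 0.312, and Dbp at ZT 11.7 and ZT 10.4. The fitted shifts of Nfil3 and Wee1 were -1.35 h and -1.55 h. Over the 25 clock list genes rhythmic with ages together the median shift was -1.09 h (permutation test, p = 0.00083; adjusted over 4 comparisons, p = 0.00216), and 23 of the 25 peaked earlier, the exceptions being Hlf and Lonrf3. Without the 6 arrays with liver transcripts, an alternative chosen after seeing the data, the median shift was -0.67 h and no longer passed the test (permutation test, p = 0.0772).

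**Figure D2:**
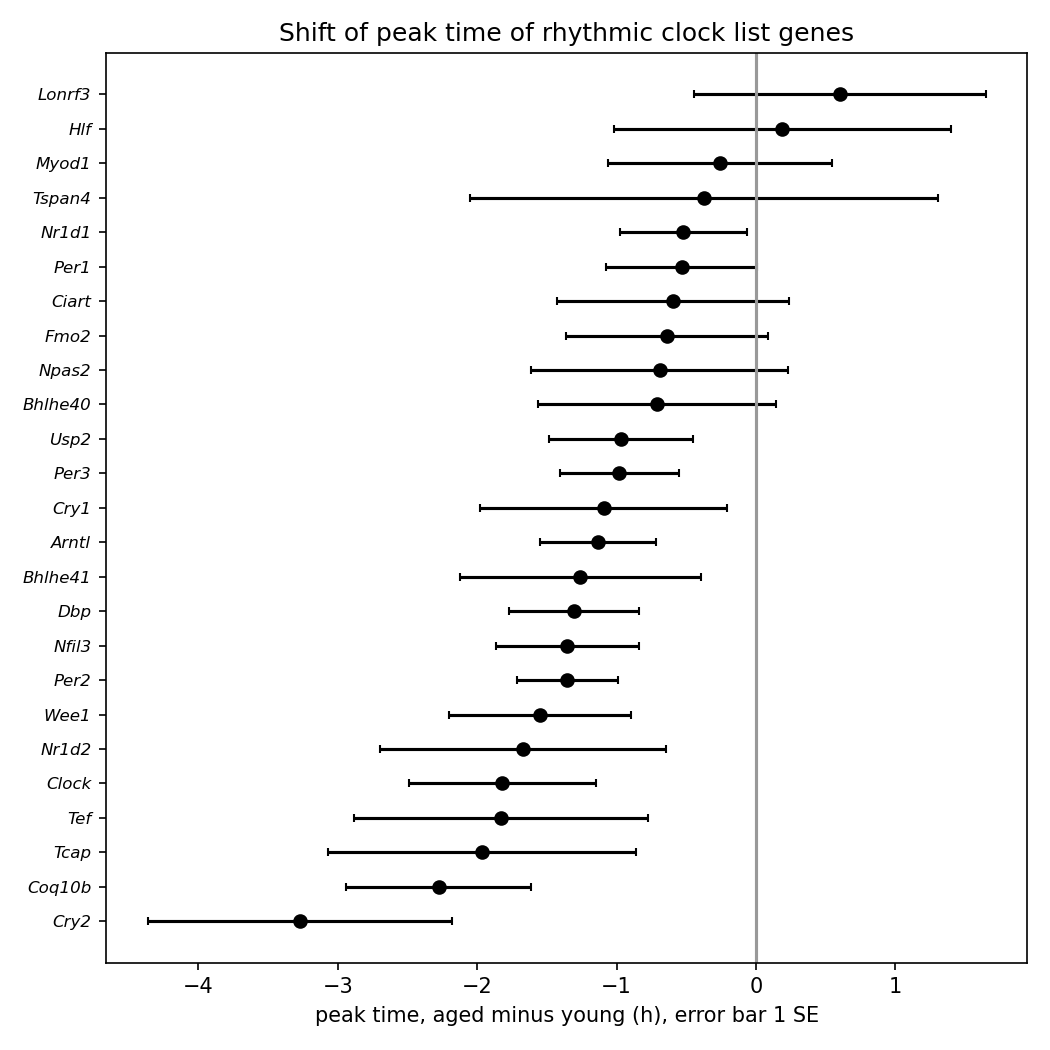
Shift of peak time in h, aged minus young (horizontal axis), of the 25 rhythmic clock list genes (vertical axis), with bars of 1 standard error. The shifts of 23 genes lie below 0, with Cry2 at -3.27 h farthest, and Lonrf3 at 0.60 h lies highest.

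The amplitude of the clock genes did not differ between ages past the threshold. The median log2 amplitude ratio of aged over young was -0.13 (permutation test, p = 0.232; adjusted p = 0.232), and 17 of the 25 genes had a smaller amplitude in aged, among them Npas2 (0.96 in young and 0.61 in aged). Over all 837 rhythmic genes the median ratio was -0.24, a change of -15.3% (permutation test, p = 0.00108; adjusted p = 0.00216), and 593 of these genes had a smaller amplitude in aged. Fkbp5 (0.77 and 0.46), Ppp1r3c (0.88 and 0.56) and Kdr (0.48 and 0.22) were among them, while Dbp (0.99 and 1.08) was not. The peak time of the 837 genes moved by a median of -0.31 h, which did not pass the test (permutation test, p = 0.114; adjusted p = 0.152).

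No single gene passed the test of a rhythm that differs with age. The genes with the smallest p were Ighv11-1, Zfp579 and Frrs1 (limma adjusted p = 0.435 each), and Per2 had an unadjusted p of 0.000944 (limma adjusted p = 0.645). At an unadjusted p under 0.05 limma gave 1293 genes, where 1164 are expected by chance. The 322 genes rhythmic in young and not past the threshold in aged, and the 36 of the reverse kind, are therefore not shown to differ in rhythm. The age difference depended on ZT in 0 genes by limma, with 771 at an unadjusted p under 0.05, led by Adh7 and Cyp4a14.

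A component of 12 h was found in 2 genes, Banp and Arntl. Banp, which encodes a nuclear matrix protein, had a 12 h amplitude of 0.34 with peaks at ZT 5.59 and ZT 17.6 (adjusted p = 2.93e-05). Arntl had a 12 h amplitude of 0.24 with peaks at ZT 4.89 and ZT 16.9 (adjusted p = 0.0350). The peak times given for both genes are those of the 12 h term alone. The level of Arntl did not peak at these times. In young replicate 1 it fell steadily from 9.71 at ZT 0 to 7.26 at ZT 12 and rose steadily to 9.38 at ZT 21. At an unadjusted p under 0.05 limma gave 905 genes. Without the 6 arrays with liver transcripts, and without any of several single arrays, the count of genes with a 12-h component was 1.

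Aged muscle differed from young muscle in many genes, by small amounts. Among the genes highest above young were the immunoglobulin genes Igkc (6.02-fold) and Ighg2c (5.24-fold), which plasma cells express. Igkv14-126 was higher as well, at 5.75 in aged and 3.05 in young, a level near the low end of the arrays at which its fold is not well determined. Among genes of muscle fibres, Kcnab1, a potassium channel subunit gene, was 3.64-fold higher (8.44 ± 0.26 in aged and 6.58 ± 0.34 in young, SD, n = 16 each; adjusted p = 2.17e-13). Ostn, which encodes the secreted peptide musclin, was 2.95-fold higher, and Ankrd1, a gene that responds to muscle stretch, 2.79-fold higher. Actc1, the cardiac and developmental actin gene, had the largest fall, with a log2 difference of -1.73 ± 0.18 (SE) and 12.8 in young against 11.1 in aged (adjusted p = 9.09e-08).

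In all, 2250 genes were higher and 1748 lower in aged muscle, 9.67% and 7.51% of those tested, while the median difference of all genes was -0.0085. At 1.5-fold or more 100 were higher and 68 lower, and at 2-fold or more 26 and 12. The 12 largest rises also held Mss51, Dkk3, Stk26, Ighv14-4, Igfn1 and Ighj4, and the 12 largest falls also held Mettl21e, Snord57, Nrep, AF357425, B230312C02Rik, AF357355, C130080G10Rik, Chad, Rian, Ibsp and Aqp4. The age difference of Chad missed the threshold without the 6 arrays with liver transcripts (adjusted p = 0.0576) at a size, -0.99, that differed little from that over all arrays, and was -0.16 without replicate 2 (adjusted p = 0.834). Nrep, a gene expressed in regenerating tissue, fell by 1.14 on the log2 scale, and Aqp4, the water channel of fast fibres, by 0.93. Within repeat 1 alone 1617 genes passed the threshold and within repeat 2 alone 1781, of which 515 were shared in the same direction, where independent lists of these sizes would share 62.5, and 3 in opposite directions.

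The lists of denervation and the junction and of immediate early genes were higher in aged muscle by camera at the preset correlation. Of 17 measured genes of denervation and the junction 7 rose and 1 fell (8 and 2 adjusted over the list alone), with Musk, the receptor kinase of the junction, higher by 0.52 ± 0.069 (SE) on the log2 scale, Chrnb1, an acetylcholine receptor subunit gene, 1.34-fold and Hdac4 1.20-fold. The list was higher by camera (adjusted p = 0.0164), with adjusted p = 0.587 with an estimated correlation, and missed the threshold with the filter on level (adjusted p = 0.301), without replicate 1 (adjusted p = 0.316) and without the 6 arrays with liver transcripts (adjusted p = 0.0595). Of 12 immediate early genes 5 rose (6 higher and 1 lower adjusted over the list alone), with Fos 1.76-fold and Egr1 1.61-fold higher (camera adjusted p = 0.0117; adjusted p = 0.587 with an estimated correlation, 0.152 with the filter on level and 0.0878 without replicate 1). The mean of these 12 genes per array was 7.30 ± 0.25 in aged and 7.06 ± 0.13 in young (SD, n = 16; permutation test, p = 0.00019), with aged ZT 9 replicate 1 highest at 8.11. Without that array the age difference of Fos was 0.70 (adjusted p = 0.000102) and the age difference of Egr1 was 0.54 (adjusted p = 5.09e-05).

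The macrophage and adipocyte lists were higher in aged muscle by camera at the preset correlation. Of 12 macrophage genes 3 rose (5 adjusted over the list alone), Cd163 1.40-fold, Mrc1 1.39-fold and Mpeg1 1.31-fold (list by camera adjusted p = 0.00157; adjusted p = 0.587 with an estimated correlation). The age difference of Mpeg1 was 0.39 over all arrays and 0.41 without the 6 arrays with liver transcripts, where it missed the threshold (adjusted p = 0.0722). Aged ZT 15 replicate 2 had the highest macrophage mean, 7.45, and without it the age difference of Cd163 was 0.47, the age difference of Mrc1 0.41 and the age difference of Mpeg1 0.34, all past the threshold. Of 8 B and plasma cell genes 3 rose (3 higher and 1 lower adjusted over the list alone), Igkc, Jchain (1.92-fold) and Ighm (1.75-fold), and the list missed the threshold (camera adjusted p = 0.0595). Of 8 adipocyte genes 0 passed over all genes and 5 were higher adjusted over the list alone. Their median log2 difference was 0.58, with Lep at 0.91 ± 0.33 (SE) and Adipoq at 0.94 ± 0.35 (camera adjusted p = 0.0159; adjusted p = 0.691 with an estimated correlation, 0.152 with the filter on level, 0.435 without replicate 1 and 0.0609 without the 6 arrays). The adipocyte mean varied from 6.31 to 9.25 between arrays, within both ages.

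The respiratory chain and slow fibre lists were lower in aged muscle by camera at the preset correlation. Of 24 genes of oxidative phosphorylation and the tricarboxylic acid cycle 11 fell and 0 rose (13 and 0 adjusted over the list alone), with Sdhc at a log2 difference of -0.66 ± 0.11 (SE), Cox5a at -0.48 and Cox4i1 at -0.39 (camera adjusted p = 6.10e-08; adjusted p = 0.567 with an estimated correlation). Of 12 slow fibre genes 7 fell (7 adjusted over the list alone), with Myh7, the slow myosin heavy chain gene, at -0.84 ± 0.23 (SE) and Tnnc1 at -0.83 (camera adjusted p = 0.00171; adjusted p = 0.691 with an estimated correlation and 0.167 without replicate 1). The age difference of Myh7 was -0.59 with the adipocyte mean as a covariate (adjusted p = 0.0874), and without replicate 1 it was -0.50 (adjusted p = 0.265) and the age difference of Tnnc1 -0.53 (adjusted p = 0.120). Of 13 fast fibre genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0663), Casq1, Mylpf and Pvalb. The slow minus fast fibre mean was -4.21 ± 0.69 in aged and -3.81 ± 0.43 in young (SD, n = 16; permutation test, p = 0.0299; adjusted p = 0.0598).

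The matrix, endothelial and satellite cell lists were lower by camera at the preset correlation as well. Of 21 collagen and matrix genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with Col1a1 at -1.16 ± 0.28 (SE) and Sparc at -0.64 (camera adjusted p = 0.00342; adjusted p = 0.711 with an estimated correlation). The aged array ZT 15 replicate 2 stood apart with Col1a1 at 12.1, against 8.28 in its repeat. Of 10 endothelial genes 7 fell (8 adjusted over the list alone), with Tie1 at -0.31 and Cdh5 at -0.25 (camera adjusted p = 0.00109; adjusted p = 0.567 with an estimated correlation). Of 8 satellite cell genes 2 fell (3 adjusted over the list alone), Calcr at -0.35 and Pax7, the marker of muscle stem cells, at -0.27 (camera adjusted p = 0.0282; adjusted p = 0.567 with an estimated correlation, 0.152 with the filter on level, 0.0873 without replicate 1 and 0.100 without replicate 2). Of 8 tenocyte genes 3 fell (1 higher and 5 lower adjusted over the list alone), among them Kera at -0.87 (camera adjusted p = 0.0595). The tenocyte list passed as lower without replicate 1 but not without replicate 2, so its difference depended on the repeat number.

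**Figure D3:**
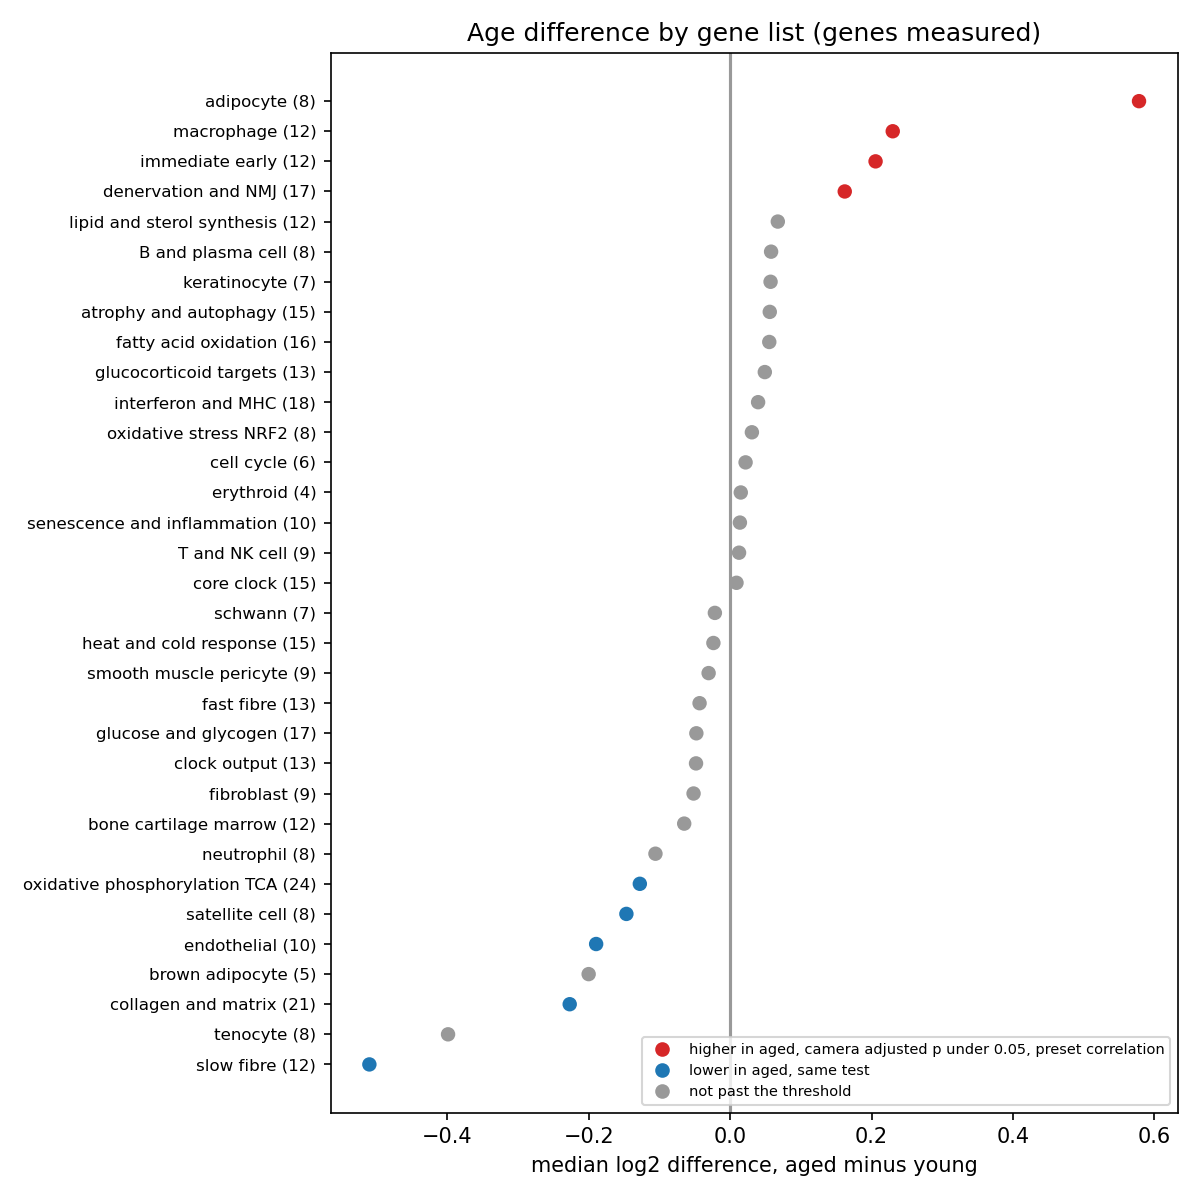
Median log2 difference, aged minus young (horizontal axis), of each fixed gene list except the sex-linked one (vertical axis, genes measured in parentheses), coloured by camera with a preset correlation of 0.01. The adipocyte list lies highest at 0.58 and the slow fibre list lowest at -0.51.

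The other lists were not past the threshold of camera with age. Of 15 core clock genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Clock 1.24-fold and Rora 1.20-fold higher, and 0 of 13 clock output genes passed (0 adjusted over the list alone). Of 13 glucocorticoid targets 2 rose (3 adjusted over the list alone), Mt1 and Mt2, which encode metallothioneins. Of 8 oxidative stress genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Nqo1 1.31-fold higher. The rises there again include Mt1 and Mt2, which are in both lists. Of 15 heat and cold response genes 6 rose and 1 fell (6 and 2 adjusted over the list alone), and of 17 glucose and glycogen genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with Pgam2 at -0.34. Of 15 atrophy and autophagy genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with the ubiquitin ligase gene Fbxo32 1.46-fold higher and Ctsl at -0.27. Of 16 fatty acid oxidation genes only Cpt2 passed, at -0.30 (1 lower adjusted over the list alone). Of 12 lipid and sterol synthesis genes 2 rose (2 adjusted over the list alone), of 18 interferon and MHC genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), and of 10 senescence and inflammation genes 1 rose and 1 fell (2 and 1 adjusted over the list alone).

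Among markers of further cell types, of 9 smooth muscle and pericyte genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), with Pdgfrb at -0.34, of 7 Schwann cell genes 1 fell (1 adjusted over the list alone), Pmp22 at -0.67 (-0.35 without replicate 2, adjusted p = 0.194), and of 12 bone, cartilage and marrow genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), Ibsp among them. Of 9 fibroblast genes 1 fell (3 higher and 2 lower adjusted over the list alone), of 8 neutrophil genes 1 fell (0 adjusted over the list alone), and of 5 brown adipocyte genes 1 fell (1 adjusted over the list alone), which was Cox7a1, also a gene of the respiratory chain. In the lists of the cell cycle (6 genes), erythroid cells (4), T and NK cells (9) and keratinocytes (7), 0 genes passed over all genes and 0 adjusted over the list alone. Of the 4 sex-linked genes measured 2 rose (2 adjusted over the list alone), Uty 1.28-fold and Eif2s3y 1.15-fold. The age difference of Eif2s3y was 0.21 over all arrays, 0.17 without the 6 arrays with liver transcripts (adjusted p = 0.203) and 0.17 with quantile normalisation again (adjusted p = 0.0828), so that its call is not firm.

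Transcripts of liver were high on some arrays. Alb, the gene of serum albumin, averaged 11.7 on 6 arrays and 8.30 on the other 26. Alb reached 12.6 on young ZT 6 replicate 1. High Alb was the rule that picked the 6 arrays, so the gap in Alb follows from that choice. The 6 arrays were young ZT 0 replicate 1, young ZT 3 replicate 1, both repeats of young ZT 6, young ZT 18 replicate 2 and aged ZT 6 replicate 1. The mean of 18 hepatocyte genes was 6.43 ± 1.47 in young and 5.57 ± 0.72 in aged (SD, n = 16; permutation test, p = 0.0265; adjusted p = 0.0598), and 5 of the 18 were lower in aged (10 adjusted over the list alone). Without the 6 arrays the count of genes higher in aged was 1555 and that of genes lower in aged 1255.

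**Figure D4:**
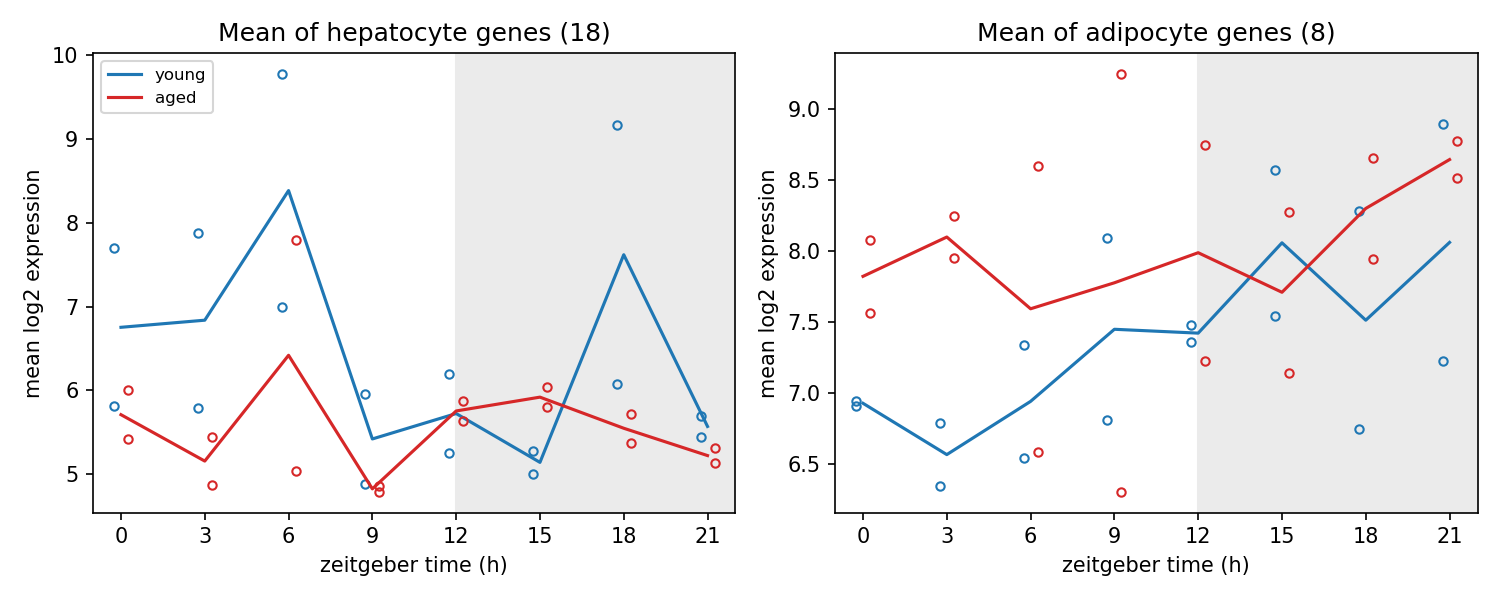
Mean log2 expression of 18 hepatocyte genes and of 8 adipocyte genes (vertical axes) against zeitgeber time in h, with each array as an open circle, lines through the means of 2 arrays, young in blue and aged in red, and the dark phase shaded. The hepatocyte mean runs from 4.79 to 9.78 and differs widely between repeats, and the adipocyte mean from 6.31 to 9.25.

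The spread between repeats did not differ between ages past the threshold. The median standard deviation between pools was 0.173 in young and 0.172 in aged, and the median log2 ratio of variances was -0.012 (exact permutation test, p = 0.953). With the filter on level the ratio was 0.31 (exact permutation test, p = 0.195). It was 0.32 without the 6 arrays with liver transcripts (exact permutation test, p = 0.125, the smallest p that 16 swaps allow), so that a difference in the spread between repeats cannot be ruled out there. Pools of 3 mice hide the spread between animals.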

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

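The comparison with other rhythmic genes, the comparison of spread, the difference and the correlation of repeats in hepatocyte genes, and every value without the 6 arrays, were chosen after the results concerned had been seen. A difference between the ages flagged the median peak shift of the 25 rhythmic clock genes, -1.09 h, and the median log2 amplitude ratio of the 837 rhythmic genes, -0.24.

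The earlier peaks of clock genes in aged muscle stay open to technical explanations. If aged mice had been taken later than the nominal times, other rhythmic genes would shift as far. The clock genes shifted by -0.66 h more than 117 other rhythmic genes with an amplitude of 0.336 or more (permutation test, p = 0.0484). This bound was the lower quartile of the clock gene amplitudes, and the 117 genes were not otherwise matched in amplitude. Their own median shift was -0.43 h (permutation test, p = 0.0589). Without the 6 arrays with liver transcripts the difference was -0.38 h (permutation test, p = 0.297), so that a general offset cannot be excluded. Liver RNA in some arrays may account for part of the shift, which was -0.67 h without those arrays (permutation test, p = 0.0772). Only 24 of 2000 random removals of 5 young and 1 aged arrays left a shift as small. These removals took no account of ZT, while the 6 arrays include both repeats of young ZT 6. The loss of that time point was thus not set apart from liver RNA. Within a single repeat the shifts were -1.03 h (permutation test, p = 0.0633) and -0.98 h (permutation test, p = 0.0147), so neither repeat alone carried it, but the former did not pass the test. A difference of the clock with age remains as an open, untested explanation.

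The smaller rhythms in aged muscle were not ended by leaving out the arrays with liver transcripts, where the median log2 amplitude ratio was -0.29 (permutation test, p = 0.0018). This argues against liver RNA on those 6 arrays as the cause of the smaller amplitudes. It does not cover the other arrays, where Alb ran from 6.4 to 9.7, and 5 of the 6 arrays left out were young. In the joint fit both ages share the same estimate of the spread. A larger spread between pools in aged would then not by itself put the count of rhythmic genes in aged below that in young. With each age fitted alone it could. The log2 variance ratio was -0.012 over all arrays (exact permutation test, p = 0.953) but 0.31 with the filter on level (exact permutation test, p = 0.195). It was 0.32 without the 6 arrays (exact permutation test, p = 0.125, the smallest that 16 swaps allow). For the counts with each age fitted alone, a larger spread thus cannot be told apart from a change of rhythm. When ages were swapped within ZT, 1 of 100 splits, the real one, gave a difference of the rhythmic counts as large as 286. The highest other was 282, so the margin was small. Genes were not centred per age before these swaps, so age differences in level can change the rhythmic counts of a split. These splits therefore cannot decide whether the gap is due to chance. With array weights the count of genes rhythmic in aged rose from 162 to 255, against 483 genes rhythmic in young, so that the size of the gap depends on the weight of single arrays. A difference with age remains as an open, untested explanation.

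The liver transcripts on 6 arrays are consistent with liver tissue or RNA in those samples. Of 20 further hepatocyte genes, listed before their values were looked at, 17 were measured, all 17 were higher on the 6 arrays and 12 by more than 1 on the log2 scale, with a median of 1.38. Expression in muscle set by age and time of day would make repeats alike. In the 5 groups that hold the 6 arrays the mean of these 17 genes differed between repeats by a median of 1.09 (0.98 to 2.07). In the other 11 groups the median was 0.056 and the highest 0.39. The 5 groups were picked by Alb on single arrays, and in only 1 of them were both repeats picked. The choice thus favours a large difference there, and the contrast with the other groups is not a separate test. The values show that arrays of the same age and ZT differed widely in these genes, which age and time of day alone would not give. Over all 16 groups, none picked by level, the intraclass correlation of the repeats was 0.122. Its 95% limits were -0.261 to 0.277 by bootstrap and -0.371 to 0.568 by the F distribution. A value under 1 arises for any genes measured in separate pools, and no other genes were compared, so the correlation does not decide between these causes. A part set by age and time of day is not ruled out. The 6 arrays were picked by their high Alb, 11.7 against 8.30 on the other 26. The gap in Alb thus follows from the choice and is not a test of liver RNA. Mup3, at 10.8 on the 6 arrays against 7.06, is in the list added after the data had been seen. No step of dissection is given in the sources used here that would settle whether liver RNA got into the samples, and how.

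Most counts were seldom reached in 100 splits each, the real one included, which makes chance less likely but cannot exclude it. The margin was small for the 12 h component, and for the count in aged another split gave more genes than the real one. With ZT permuted within each age, 1 split gave as many genes as the 448 rhythmic in young (highest other 23), 2 as many as the 162 in aged (highest other 257), 1 as many as the 837 together (highest other 3) and 1 as many as the 2 with a 12 h component (highest other 1). With ages swapped within ZT, 1 split gave as many as the 3998 genes that differ with age (highest other 1). For the 0 genes whose rhythm differs with age and the 0 whose age difference depends on ZT all 100 splits gave as many, as any split gives 0 or more, so the splits cannot speak to chance for these counts, and the highest others were 727 and 1. Genes were not centred per age before these swaps, so real age differences in level can enter the rhythm terms of a split. The source of the 727 genes was not tested.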

How the results depend on the processing

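The covariates for hepatocyte genes, adipocyte genes and array range, the random block and the setting without 6 arrays were chosen after seeing the data. Under the settings that kept all arrays, and without the 6, the counts of genes higher in aged and of genes lower in aged stayed within 1.5 times of 2250 and 1748, except with a fold of 1.5 or more besides (100 and 68, by construction), and were 1735 and 1179 with age by repeat as a random block. The counts of genes rhythmic in young, of genes rhythmic in aged and of genes rhythmic with ages together moved with ZT as a factor (104 in young, 32 in aged, 309 together), with each age fitted alone (292 and 98), with array weights (255 in aged) and without the 6 arrays with liver transcripts (255 in young). The count of genes with a 12-h component was 1 with centred arrays, array weights, the hepatocyte covariate and without the 6 arrays. The gene lists higher in aged were 1 with the filter on level, 2 without the 6 arrays and 0 with an estimated correlation, and the gene lists lower in aged were 0 with an estimated correlation. The filter kept the macrophage list (adjusted p = 0.0448) and ended those of denervation (0.301), immediate early genes (0.152), adipocytes (0.152) and, among the lower lists, satellite cells (0.152). Without the 6 arrays the denervation (0.0595) and adipocyte (0.0609) lists missed the threshold, and fast fibres joined the lower lists (0.0367). All 9 called lists passed without any single array of the 32, but 5 missed the threshold without replicate 1, those of denervation (0.316), immediate early genes (0.0878), adipocytes (0.435), slow fibres (0.167) and satellite cells (0.0873), the last also without replicate 2 (0.100). The clock gene phase shift was -0.67 h without the 6 arrays, and the rhythmic gene phase shift -0.39 h over genes with adjusted p under 0.01 (permutation test, p = 0.0385). The log2 ratio of the spread between repeats turned to 0.0074 with centred arrays, 0.31 with the filter on level (exact permutation test, p = 0.195) and 0.32 without the 6 arrays (p = 0.125, the smallest that 16 swaps allow). The cause was not tested for these, apart from fewer samples where arrays were left out. With an array or a repeat number left out, the ranges were 35 to 490 genes rhythmic in young, 8 to 181 in aged, 150 to 917 together, 0 to 1 genes whose rhythm differs with age (1 without aged ZT 18 replicate 2), 926 to 2450 higher and 609 to 1981 lower in aged, 0 to 11 genes whose age difference depends on ZT, 0 to 3 with a 12 h component, -1.24 to -0.76 h for the clock gene shift, -0.19 to -0.062 for the clock gene amplitude ratio, -0.40 to -0.18 h for the rhythmic gene phase shift, -0.28 to -0.17 for the rhythmic gene amplitude ratio, -0.14 to 0.070 for the spread ratio, and 1 to 6, 4 to 7 and 4 to 10 lists higher, lower and enriched in rhythmic genes. The lowest counts came without replicate 1 or 2, which leaves 1 array per group, assumed to vary like the others. There neither the dependence on ZT nor the spread could be tested, and without the 6 arrays, which hold both of young ZT 6, dependence on ZT was not run. Without aged ZT 15 replicate 1 the age difference depended on ZT in 11 genes, and without aged ZT 6 replicate 2 in 7. With the repeat number as a replicate block 2319 genes were higher and 1855 lower in aged, but the rhythm of C1qc was lost (adjusted p = 0.0530). With ZT by repeat as the block, 2206 were higher and 1738 lower, the age differences of Ifit1, Ccl8, Camp and Eif2s3y were lost (adjusted p = 0.0684, 0.0637, 0.0543 and 0.0660) and those of Retn, Lep, Adipoq and Acvr1c gained (adjusted p = 0.0267, 0.0146, 0.0308 and 0.0404). The deviations of same-numbered arrays of both ages correlated at -0.028 to 0.13 per ZT, so the numbers were not taken to pair the arrays. Of the named genes past the threshold with age, and the adipocyte genes named by the rule, 0 turned direction under these settings. With all arrays kept 1456 values of the age difference kept their side of the threshold, 76 lost it and 14 gained it, and of rhythm 681, 31 and 2. For age 91 were kept and 13 lost without the 6 arrays, and 59 and 6 for rhythm, and with a replicate or array left out 3283 were kept, 221 lost and 32 gained for age, and 2092, 111 and 7 for rhythm. For weakly expressed genes signal over background limits what can be seen.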

Other observations

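The groups of genes in this part, and the tests of groups and of repeats, were chosen after the data had been seen. The age differences of single genes come from the planned test. Some transcripts of the imprinted region between Dlk1 and Dio3, a neighbourhood rich in maternally expressed noncoding RNA genes, were lower in aged muscle. Of 67 tested genes there 16 fell and 0 rose (Fisher's exact test for falling genes, one-sided, p = 2.72e-05, which takes genes as independent although they share transcripts). Meg3 fell by 0.90 on the log2 scale (SE 0.095, adjusted p = 1.19e-07) and Rian by 0.99, at all 8 ZT. Of 6 small nucleolar RNA genes there 5 fell, AF357425 by 1.13 and AF357355 by 1.09 (the latter by 0.54 without replicate 1, adjusted p = 0.337), and of 52 microRNA genes 9 fell. Of 100 small nucleolar RNA genes elsewhere 2 fell and 17 rose.

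Immunoglobulin genes formed another group. Of 216 probe sets of immunoglobulin heavy, kappa and lambda genes 30 rose and 5 fell with age, with a median difference of 0.032, so that most did not change past the threshold. Some of these genes are close copies of each other, and probes can be shared between those.

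Snord57 fell with age to different degrees in the repeats. Its level was 10.02 ± 0.23 and 9.79 ± 0.19 in repeats 1 and 2 of young and 9.60 ± 0.19 and 7.77 ± 0.65 in those of aged (SD, n = 8 each; limma adjusted p = 0.00187 for the interaction of age and repeat). In all 246 genes had such an interaction, 2931 at an unadjusted p under 0.05. The repeats differed in 43 genes within young and in 161 within aged. The 4 sets of 8 arrays, each of 1 age and 1 repeat number, may have been processed as batches, which the sources used here do not settle. A batch difference between the ages cannot be told apart from age. With age by repeat as a random block the count of genes higher in aged was 1735 and that of genes lower in aged 1179, against 2250 and 1748. On the aged array ZT 15 replicate 2, Postn was at 11.4 against 6.22 in its repeat, and the mean of the matrix genes was 9.76, the highest of the 32 arrays.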
